A study of Homo sapiens with 2 samples.

How the data were processed

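Gene expression was measured by RNA sequencing in 2 libraries of human kidney tubule, which form 1 group. Per the labels, the tissue was the non-tumour part of surgically removed kidneys or what remained of diagnostic biopsies, it was kept in an RNA preservative, and tubules were separated from glomeruli by hand under a microscope. Complementary DNA was primed with oligo-dT, so that polyadenylated RNA was favoured, and was sequenced as single-end reads on an Illumina instrument. The labels' sample protocol and the series' design text name different RNA extraction kits and different minimums of RNA integrity. They do not say whether the 2 samples came from separate persons, so the spread between the libraries may hold technical as well as individual differences.

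The authors deposited 1 table of gene symbols and values per library, without a header. The deposited values were taken as FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), because they were not whole numbers, summed to 301588 and 326065 over all symbols, and low values differed between the libraries at fixed steps, as whole reads divided by gene length do. The submitters' processing notes name TopHat2 2.0.9, STAR 2.3.0, Cufflinks 2.1.1 and CASAVA 1.8.2 and the GRCh37 and hg19 names of 1 human genome build, without a role or an order for each tool. The gene annotation, the filters and the treatment of strand are not given in the sources used here, so reads from overlapping or antisense genes may have been assigned to either. Estimated values of this kind can fail for single genes, and a value of exactly 0 is therefore described only as listed at 0. The tables give symbols and no positions, and the reference annotation at hand was of a later build, so no genomic coordinates are given.

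Each table held 27027 lines for 25270 symbols. The 608 symbols on several lines were summed, of which 38 and 32 had more than 1 line above 0 in libraries 1 and 2. Before the data were examined, it was decided to leave out genes whose level can tell a person's sex or genotype (sex-specific transcripts, HLA and killer cell receptor genes, antigen receptor segments, and genes with common deletions or strong inherited differences in expression). This removed 203 symbols and left 25067. None of the 13 mitochondrially encoded protein genes listed beforehand was among the symbols analysed, so the share of mitochondrial transcripts was not analysed here.

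Read depth is not stated in the tables, and was inferred from the steps of low values. Among 2801 genes between 0.001 and 0.3 FPKM in both libraries, the most common ratio of library 1 to library 2 was 0.961, at which 340 genes lay when ratios were rounded to 3 decimals. That is the ratio left when both libraries hold the same number of reads in a gene and library 1 is 1.04 times as deep. The value of 1 read in olfactory and trace amine receptor genes, with their coding lengths from GENCODE and an assumed fragment length of 200 nucleotides, gave 32300000 reads for library 1 (at 4 of 9 genes) and 31100000 for library 2 (9 of 15 genes). At these depths a gene of 2 kb at 5 FPKM would rest on 323 and 311 reads, and counting alone would give its log2 ratio a standard error of 0.11. This error covers counting only.

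With 1 group of 2 libraries there was no comparison of groups, no significance test was run and no p-value was computed. Levels are given per library or as mean ± SD over the 2 libraries (n = 2). The ratio of a gene was the difference of log2(FPKM + 1), library 2 minus library 1, a scale on which the pseudocount of 1 FPKM understates the change of low genes, and every fold given is on this scale. A gene was counted as detected at 1 FPKM or more, and as differing at least 4-fold by its log2 ratio if its mean was at least 5 FPKM. Agreement was computed across genes with a mean of at least 1 FPKM, and genes are not independent replicates.

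Before the data were examined, 35 gene lists were fixed from general knowledge of the kidney, of which 34 had a measured member. They covered nephron segments (proximal tubule and its convoluted and straight parts, thin limb, thick ascending limb, distal convoluted tubule, connecting tubule and principal cell, intercalated cell), other cell types (podocyte, endothelium, smooth muscle and mesangium, fibroblast and matrix, T and NK cell, B and plasma cell, myeloid cell, red blood cell) and functions. A list's level was the median over its measured members in each library. Its ratio was the median log2 ratio of members above 0 and was set against 10000 random lists of the same size, each member drawn from the same of 20 bins of mean expression. A list was called higher in 1 library when its ratio lay outside the central 95% of these random lists, which describes these 2 libraries and is no test of a condition. Members were counted as at least 2-fold apart among those with a mean of at least 1 FPKM.

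The genes to be named were also chosen by a rule set beforehand: the 20 genes of highest mean, the 4 most abundant members of each list with its member of largest ratio at a mean of at least 5 FPKM, and the 10 genes of largest ratio in each direction at a mean of at least 20 FPKM. Some genes that the rule takes are not reported here. Other members of the fixed lists and solute carrier genes are named in places, chosen after their values were seen.

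The calculation was tested on simulated data of the comparison of library 2 with library 1, over 25067 genes with counting noise and a log2 SD of 0.18 per library. Of 200 genes planted with an 8-fold change, 199 passed the 4-fold rule, as did 0 of 7669 unchanged genes. The noise was normal, and its SD came from the median absolute deviation of these libraries' own ratios. Unchanged genes could thus hardly pass the 4-fold rule, and the count of 0 gives no false call rate for the real data. The 4 lists of 15 genes planted with shifts of 1, -1, 0.5 and -0.5 came out at 0.76, -0.82, 0.30 and -0.58, all outside their random range, and 8 of 200 unchanged lists fell outside theirs. Every simulated gene had a length of 2 kb and noise independent of other genes. The outcome therefore does not carry over to short genes, such as small RNA genes, or to lists whose members vary together.

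The alternatives planned beforehand were other detection thresholds, a pseudocount of 0.1 FPKM, other filters on low values, means over members in place of medians, scaling by the median ratio of expressed genes, and leaving out each library. An alternative without small RNA genes and a further filter on list members were added after the data were seen. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.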

Results

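The data describe the transcriptome of tubules dissected from human kidney tissue without tumour, in 2 libraries of 1 group, called library 1 and library 2 here. The series set out to give a quantitative account of gene expression in normal human kidney, and with 1 group the comparisons are between gene groups within each library and between the libraries. The depth inferred from the values was 32300000 reads for library 1 and 31100000 for library 2. Values are FPKM, ratios are of FPKM + 1 in library 2 over library 1, and the genes are given by symbol without coordinates.

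The most abundant transcript in both libraries was GPX3, which encodes the secreted glutathione peroxidase of plasma, at 6984 and 10184 FPKM in libraries 1 and 2. Among the next by mean level were FTL, the ferritin light chain (4394 ± 265 FPKM, SD, n = 2), the metallothionein gene MT1G (3287 ± 0.629) and UMOD, which encodes the uromodulin of the thick ascending limb (2349.6 ± 548). SPP1, encoding osteopontin, stood at 3209.8 and 1362 FPKM and B2M, the light chain of class I antigen-presenting molecules, at 877 and 2623. The 16 genes shared by the 20 most abundant of each library did not include the interferon-induced IFI6, which lay at 22.6 and 2103 FPKM. The 10 most abundant genes held 9.78% of the summed FPKM in library 1 and 10.2% in library 2 (SD 0.302, n = 2), the top 50 held 19.8% ± 0.180 and the top 100 held 26.8% ± 0.195. At least 1 FPKM was reached by 12492 genes in library 1, by 12813 in library 2 and by 12191 in both.

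Proximal tubule genes were the most abundant of the segment and cell type lists. Podocyte genes, which mark the glomerulus from which the dissection separated the tubules, lay far below them. With no glomerular or undissected sample here, this gap does not show how much glomerulus the dissection removed. The median over the 33 proximal tubule genes was 122 ± 12.5 FPKM (SD, n = 2), against 6.37 ± 4.14 FPKM over 12 podocyte genes. The difference of their median log2 values was 4.89 and 3.47 in libraries 1 and 2, with a mean of 4.18 ± 1.0 (SD, n = 2), or 18.1-fold, so that it exceeded the spread between the libraries. Among the leading proximal genes were PCK1, the rate-limiting enzyme of gluconeogenesis (1165 ± 70.3 FPKM), GATM of creatine synthesis (1111 ± 323) and MIOX of inositol breakdown (635 ± 68.6). Of the podocyte genes, PODXL, which endothelium also expresses, was measured at 21.8 and 57.9 FPKM in libraries 1 and 2, and SYNPO at 10.8 and 22.0.

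Along the nephron, the convoluted part of the proximal tubule had a median of 89.3 ± 25.2 FPKM, led by the organic anion transporter SLC22A8 (263 ± 88.7), the phosphate transporter SLC34A1 (175 ± 54.3) and SLC7A7 (108 ± 45.1). The straight part stood at 14.9 ± 4.24 FPKM, with SLC22A7 at 72.0 ± 6.38. The thick ascending limb list had a median of 30.8 ± 2.08 FPKM, with UMOD far above the others and the sodium potassium chloride cotransporter SLC12A1 at 242 ± 52.6. The thin limb list reached 33.9 ± 15.4 FPKM, which included CRYAB at 548 ± 147, and the distal convoluted tubule 13.3 ± 3.73, including the thiazide-sensitive cotransporter SLC12A3 at 27.2 and 58.8. The connecting tubule and principal cell list lay at 25.4 ± 23.2 FPKM, its median in each library being the value of SCNN1G (41.8 and 9.02). Its vasopressin-regulated water channel AQP2 stood at 513 and 203. The intercalated cell list lay at 7.59 ± 1.39, with the proton pump subunit ATP6V1B1 at 81.0 and 39.9.

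Proximal tubule genes exceeded those of the thick ascending limb by 1.96 ± 0.24 (log2, SD, n = 2), the thin limb by 1.91 ± 0.80, the distal convoluted tubule by 3.13 ± 0.53 and intercalated cells by 3.85 ± 0.09. They exceeded the straight part's own list by 2.98 ± 0.25 and the connecting tubule and principal cell list by 2.56 ± 1.33, where the libraries gave 1.62 and 3.51. That last difference was 1.01 when only members with a mean of at least 1 FPKM were used. With all members, the list's median in each library was the value of 1 gene, SCNN1G (41.8 and 9.02 FPKM), its member of largest ratio. The convoluted part lay 0.47 ± 0.55 below the full proximal list, a difference smaller than its spread.

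The lists of other cell types all had lower medians than the proximal tubule list, though not lower than every segment list. A list's median depends on its chosen members and does not measure the share of a cell type. Proximal tubule genes exceeded endothelial genes by 3.89 ± 0.60 (log2, SD, n = 2), smooth muscle and mesangial genes by 3.62 ± 1.29, fibroblast and matrix genes by 2.95 ± 0.65 and myeloid genes by 3.17 ± 0.56. The list medians were 7.48 ± 2.61 FPKM for endothelium, 10.6 ± 8.34 for smooth muscle and mesangium, 15.3 ± 5.62 for fibroblast and matrix and 12.9 ± 3.99 for myeloid cells. The most abundant members were the complement gene C7 (151 and 274 FPKM in libraries 1 and 2) and the smooth muscle gene TAGLN (110.4 and 223), and the macrophage gene CD68 led the myeloid list (32.1 and 55.8). The medians of lymphocyte and red blood cell genes were lowest, at 0.650 ± 0.192 FPKM for T and NK cells, 0.390 ± 0.0608 for B and plasma cells and 0.414 ± 0.0127 for red blood cells, with proximal differences of 6.22 ± 0.31, 6.46 ± 0.21 and 6.46 ± 0.14. These differences became 5.24, 4.03 and 4.08 with members of at least 1 FPKM (1, 2 and 2 members), and 7.37, 7.97 and 8.04 with a pseudocount of 0.1. IGJ, the joining chain gene of antibodies, led the B and plasma cell list (9.29 and 28.2 FPKM). The 2 red blood cell members with a mean of at least 1 FPKM were HBB (4.85 and 5.81) and SLC4A1, which intercalated cells also express. HBA1 and HBA2 are near-identical copies, so their values are uncertain.

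**Figure D1:**
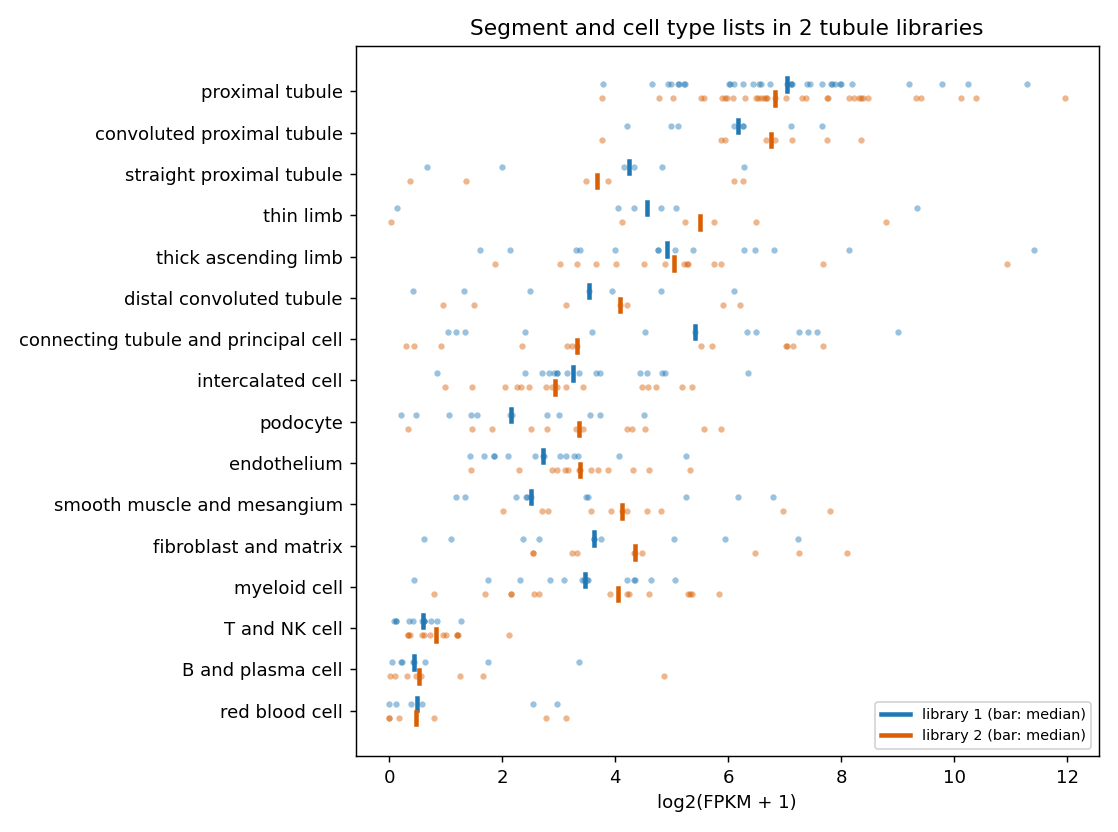
Each point is 1 gene of a nephron segment or cell type list, with its level as log2(FPKM + 1) on the horizontal axis, in blue for library 1 and orange for library 2, and the upright bars are the medians over the members. The proximal tubule bars lie above those of the podocyte list by 4.89 and 3.47 in libraries 1 and 2.

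Transporters and metabolic enzymes were prominent in both libraries. Of 363 solute carrier genes, 247 reached 1 FPKM and 13 reached 100 FPKM in both libraries, led by the amino acid transporter subunit SLC3A1 (322 ± 44.1 FPKM, SD, n = 2) and SLC25A5, the mitochondrial exchanger of adenine nucleotides (311 ± 57.9). Among water channels, AQP1 stood at 755 ± 63.7 FPKM, AQP2 at 358 ± 219 and AQP3 at 149.9 ± 27.6, while the list's median was 2.03 ± 0.0351 and 6 of its 12 members reached a mean of 1 FPKM. Drug and organic ion transporters had a median of 34.2 ± 0.796 FPKM, with the organic anion transporter SLC22A6 at 175 and 317 and the urate transporter SLC22A12 at 208 and 198. Gluconeogenesis genes had a median of 234 ± 13.2 FPKM, glycolysis genes 133 ± 45.6, fatty acid oxidation genes 61.7 ± 9.45 and nuclear genes of oxidative phosphorylation 121 ± 4.08. Within these lists, ECHS1 of fatty acid oxidation stood at 368 and 363 FPKM in libraries 1 and 2, LDHB of lactate metabolism at 951 and 837 and the respiratory chain gene COX7C at 697 and 704. In contrast, HK2, the inducible hexokinase, stood at 0.155 and 0.386 FPKM.

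Metallothionein genes had the highest list median, 649.6 ± 2.74 FPKM, followed by cytoplasmic ribosomal protein genes at 448 ± 6.46, and housekeeping genes stood at 156 ± 12.8. Kidney transcription factors had a median of 10.4 ± 1.72 FPKM, with PAX8 at 52.3 ± 7.39 and HNF4A, a regulator of the proximal tubule, at 34.5 ± 14.5. The genes of inherited tubular or cystic disease stood at 29.3 ± 2.99 FPKM, hypoxia genes at 10.6 ± 4.81, and tubular injury genes at 49.2 ± 1.23. Proliferation genes were at 1.15 ± 0.0483, with MKI67, a marker of dividing cells, at 0.0732 and 0.124 FPKM. Metallothionein genes are close paralogs and ribosomal protein genes have many processed copies, so that reads could be shared between copies and single values are uncertain.

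The libraries were close for most genes. Across 12760 genes with a mean of at least 1 FPKM, Pearson's r of log2(FPKM + 1) was 0.947 and Spearman's rho 0.939. The median absolute log2 ratio was 0.19, or 1.14-fold, and 94.8% of these genes lay within 2-fold. Among 7874 genes with a mean of at least 5 FPKM, 117 differed at least 4-fold, 90 higher in library 2 and 27 higher in library 1. Among the 90 were 15 of the 15 interferon response genes and 10 of the 15 immediate early genes. Small RNA genes, which oligo-dT priming captures poorly and which often lie inside longer host genes, were 24 of the 117. Without them, 77 and 16 genes were left. With a mean of at least 20 FPKM the counts were 43 and 11.

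**Figure D2:**
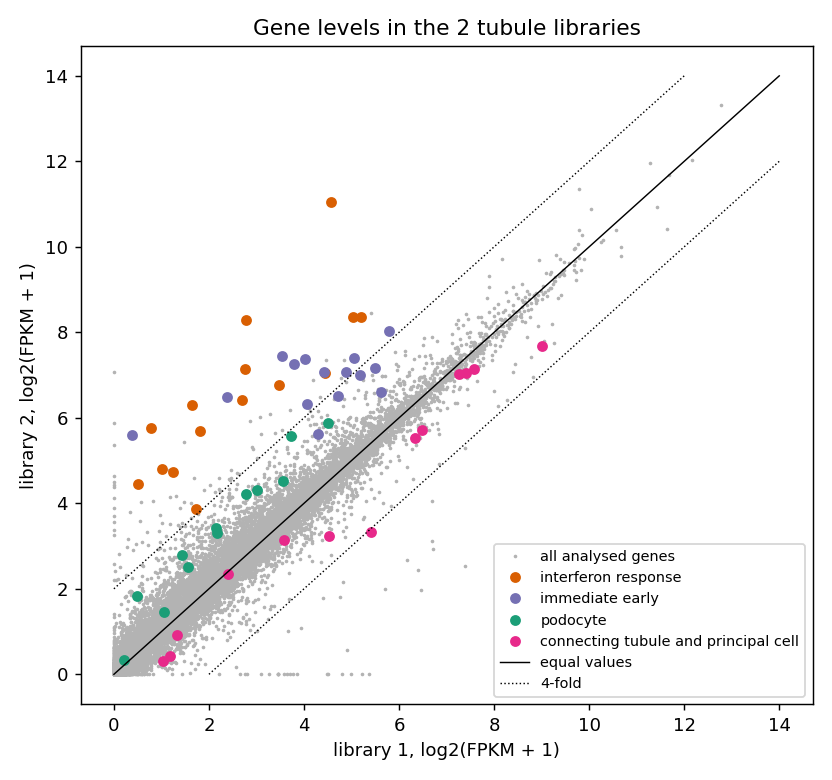
Each point is 1 analysed gene, with log2(FPKM + 1) in library 1 on the horizontal axis and in library 2 on the vertical axis. The solid line marks equal values and the dotted lines 4-fold differences, and the coloured points are the members of 4 gene lists. All 15 interferon response genes lie above the upper dotted line.

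Of the fixed lists, interferon-stimulated genes differed most between the libraries. Their median level was 5.44 and 83.8 FPKM in libraries 1 and 2. All 15 members of the interferon response list were at least 2-fold higher in library 2, and the list's median log2 ratio was 3.80, or 13.9-fold, against a range of -0.10 to 0.23 for random lists. IFI6 stood at 22.6 and 2103 FPKM in libraries 1 and 2, the ubiquitin-like ISG15 at 5.89 and 310.2, IFI27 at 31.9 and 325 and IFITM1 at 35.9 and 328. The antiviral GTPase gene MX1 stood at 5.74 and 139.9 FPKM, IFIT1 at 2.14 and 78.1 and IFI44L at 0.709 and 52.9. Both libraries belong to 1 group, so the difference has no replicate check.

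Immediate early genes, which are transcribed within minutes of a stimulus, were the list with the next largest ratio. Their median level was 20.4 and 133 FPKM and their median log2 ratio 2.26 (4.79-fold, random lists -0.11 to 0.22), and 14 of 15 members were at least 2-fold higher in library 2. FOSB stood at 0.295 and 47.7 FPKM in libraries 1 and 2, the mRNA decay factor ZFP36 at 54.3 and 259, FOS at 10.6 and 173 and JUNB at 32.4 and 168. Heat shock genes, with medians of 62.7 and 97.8 FPKM, gave a ratio of 0.20, within the random range of -0.13 to 0.27. Here HSPA8 was at 473 and 408 FPKM and HSPB1 at 210.2 and 329, and the stress-inducible HSPA6, at 0.386 and 7.23, had a mean below 5 FPKM. With the mean over members in place of the median, the heat shock ratio was 0.61, outside the random range. The near-identical copies HSPA1A and HSPA1B share reads and are uncertain.

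Genes of podocytes, vessels and stroma were higher in library 2. The podocyte list had a median log2 ratio of 1.29 (2.44-fold, random lists -0.10 to 0.26), with 8 of 11 members at least 2-fold higher in library 2 and none at least 2-fold higher in library 1. PODXL was 2.58-fold and TCF21, a transcription factor gene, 2.44-fold higher. Smooth muscle and mesangial genes had a ratio of 1.01 (6 of 11 members), fibroblast and matrix genes 0.91 (4 of 10) and endothelial genes 0.61 (3 of 14), all above their random ranges. The collagen-binding proteoglycan genes DCN and LUM stood at 60.4 and 151 FPKM and 32.0 and 87.5 FPKM in libraries 1 and 2, TAGLN at 110.4 and 223 and the vessel gene EMCN at 8.64 and 23.3.

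Of the leukocyte lists, myeloid genes had a ratio of 0.39 (random lists -0.08 to 0.24), with the complement gene C1QA at 19.4 and 40.3 FPKM and the scavenger receptor gene CD163 at 9.64 and 4.91. The T and NK cell ratio was 0.30 (random lists -0.09 to 0.22) over 12 members, of which only 1, the chemokine gene CCL5 (1.40 and 3.34 FPKM), had a mean of at least 1 FPKM. B and plasma cell genes (0.08) and red blood cell genes (0.16) lay within their random ranges, although IGJ was 2.83-fold higher. The myeloid ratio was 0.28, within the random range, with the mean over members and 0.65 with members of at least 5 FPKM, and the T and NK cell ratio was 0.98 with a pseudocount of 0.1.

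Genes of the collecting duct and thick ascending limb were lower in library 2, and those of the convoluted proximal and distal convoluted tubule higher. The connecting tubule and principal cell list had a median log2 ratio of -0.74 (random lists -0.11 to 0.25), with 3 of 11 members at least 2-fold higher in library 1. AQP2 stood at 513 and 203 FPKM and SCNN1G, a subunit of the epithelial sodium channel, at 41.8 and 9.02. Thick ascending limb genes (-0.35, random lists -0.09 to 0.23) and intercalated cell genes (-0.33, random lists -0.08 to 0.24) were also lower, as were the straight proximal genes (-0.38, random lists -0.17 to 0.38). In these lists SLC12A1 stood at 279 and 205 FPKM and ATP6V1B1 at 81.0 and 39.9, while CLDN14, a claudin of the thick ascending limb, went the other way (2.06 and 15.1), as did SLC7A13 of the straight part (27.2 and 76.1). The convoluted proximal list was higher in library 2 (0.72, random lists -0.14 to 0.31). Of its 8 members, 6 are also in the full proximal list. Also higher were the full proximal list (0.29, random lists -0.06 to 0.15), drug transporters (0.32, random lists -0.09 to 0.23) and the distal convoluted tubule (0.54, random lists -0.17 to 0.36). SLC36A2, an amino acid transporter, stood at 17.4 and 57.2 FPKM, the brush border dipeptidase gene DPEP1 at 235 and 639, and the glucose transporter gene SLC2A2 went the other way (30.8 and 12.6). When the mean over members replaced the median, the connecting tubule and principal cell and intercalated cell lists stayed outside their random ranges and the others named here fell inside. The connecting tubule and principal cell ratio was -0.43 with members of at least 1 FPKM, the intercalated cell ratio -0.19 with members of at least 5 FPKM and the straight proximal ratio -0.60 with a pseudocount of 0.1. The thin limb ratio was 0.10, within its random range, although the claudin gene CLDN4 stood at 19.2 and 89.1 FPKM.

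Metallothionein genes, which bind zinc and copper, had the lowest list ratio, -0.78 (random lists -0.16 to 0.32). With a pseudocount of 0.1 the connecting tubule and principal cell list lay slightly lower. Of the metallothionein genes, MT1G stood at 3288 and 3287 FPKM in libraries 1 and 2, MT2A at 1626 and 1028, MT1X at 1625 and 876 and MT1A at 103 and 15.6. Tubular injury genes had a ratio of -0.28 (random lists -0.10 to 0.23), with 3 of 15 members at least 2-fold higher in library 1 and none at least 2-fold higher in library 2. By any margin, 9 members were higher in library 1 and 6 in library 2. Among these 6 were SOX9 (1.98-fold) and VIM (1.82-fold), just short of 2-fold, so the list did not move as 1. SPP1 stood at 3209.8 and 1362 FPKM, CLU, encoding clusterin, at 309 and 84.9, and the keratin genes KRT8 and KRT18 at 178 and 163 FPKM and 162 and 133 FPKM. The acute phase and complement list, with medians of 19.8 and 4.82 FPKM, gave a ratio of 0.11, within its random range, because its members went both ways. Its fibrinogen chain genes FGA and FGB stood at 168 and 4.82 FPKM and 87.5 and 2.94 FPKM, and the protease inhibitor gene SERPINA1 at 439.7 and 170.4, while the complement genes C1R and C1S stood at 28.9 and 57.5 FPKM and 19.8 and 57.5 FPKM. Its direction turned with the mean over members (-1.01) and with members of at least 5 FPKM (-0.32), both below their random ranges, and with members of at least 1 FPKM (-0.10), within its random range.

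Metabolic lists differed little. Fatty acid oxidation genes were lower in library 2 (-0.24, random lists -0.08 to 0.20), with ACAA2 at 206 and 158 FPKM and ACADVL at 207 and 181. Ribosomal protein genes (-0.12, random lists -0.08 to 0.17) and glycolysis genes (-0.11, random lists -0.10 to 0.22) lay just below their ranges, and no member of either was 2-fold apart. The genes of inherited tubular disease were lower (-0.25, random lists -0.09 to 0.22), 9 of whose 17 members stand in other lists as well, and hypoxia genes were higher (0.30, random lists -0.11 to 0.26), with the vessel growth factor gene VEGFA at 30.1 and 63.7 FPKM and ADM at 61.7 and 147. Of the 10 hypoxia members with a mean of at least 1 FPKM, 3 were higher in library 1, among them LDHA (170 and 101 FPKM). The hypoxia call was lost with a pseudocount of 0.1, the glycolysis call with members of at least 5 FPKM, and the hypoxia, glycolysis and ribosomal protein calls with the mean over members. With members of at least 1 and 5 FPKM the hypoxia ratio was 0.52 and 0.81. Gluconeogenesis (0.11), nuclear oxidative phosphorylation (-0.04), aquaporins (0.01), kidney transcription factors (0.12), proliferation (0.08) and housekeeping genes (-0.10) lay within their random ranges, but aquaporins fell below theirs with members of at least 1 FPKM (-0.19). B2M, a housekeeping member that interferon also induces, stood at 877 and 2623 FPKM.

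Of the 34 lists, 23 lay outside their random range, 13 higher in library 2 and 10 higher in library 1. Random lists draw each gene on its own, so 1.7 would be expected only if the members of a list varied independently. Genes of 1 list can vary together, so 1.7 is no measure of chance for these lists. In 7 of the 23 (proximal tubule, thick ascending limb, tubular injury, metallothionein, drug transporter, inherited tubular disease and ribosomal protein), the list's median level and its median ratio pointed opposite ways. For the proximal tubule the median levels were 131 and 113 FPKM in libraries 1 and 2.

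**Figure D3:**
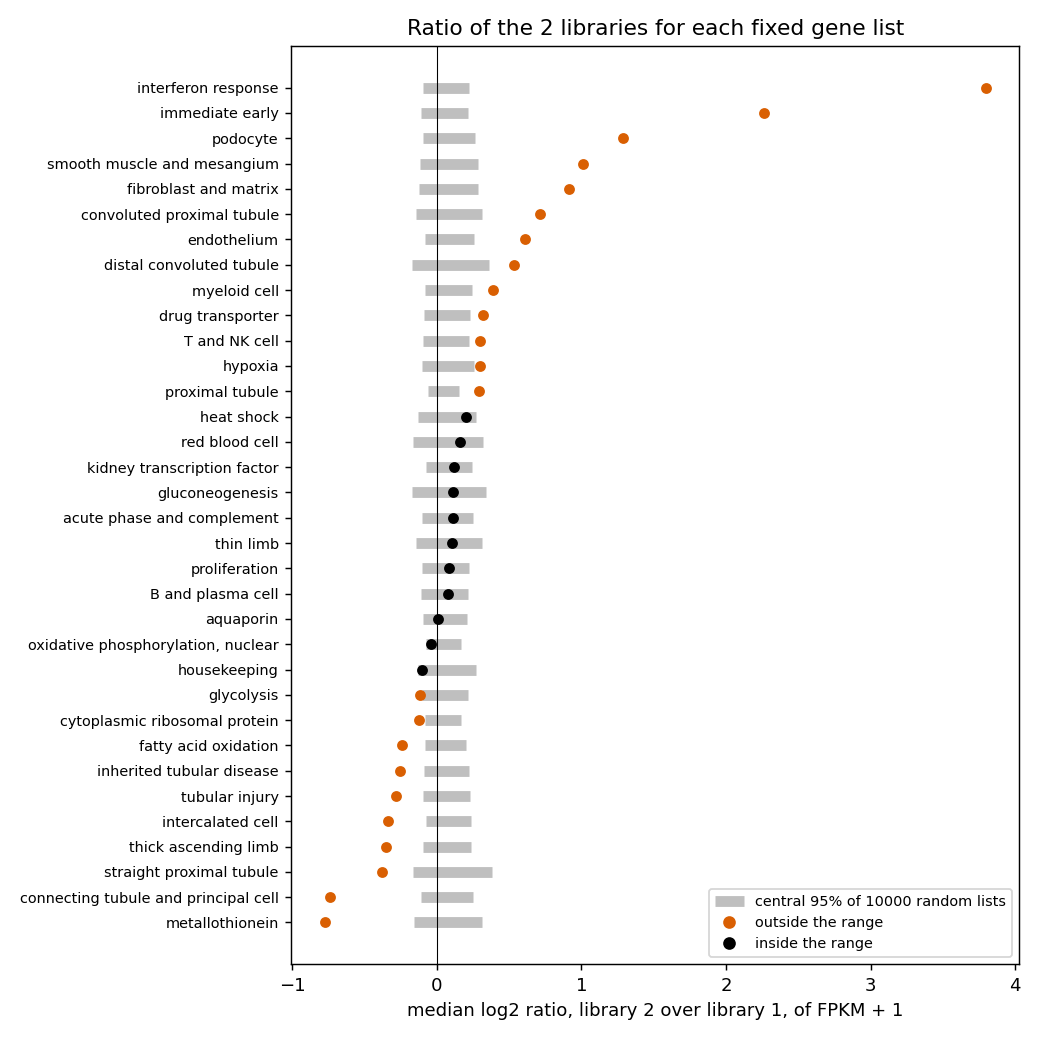
Each point is the median log2 ratio of FPKM + 1, library 2 over library 1, of 1 fixed gene list, and the grey bars span the central 95% of 10000 random lists of the same size and expression. Orange points lie outside and black points inside the bars, and the interferon response list lies at 3.80.

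The single genes of largest ratio at a mean of at least 20 FPKM included members of these lists. Toward library 2 they were IFI6, ISG15, FOSB, IFI44L, IFIT1 and MX1, the small RNA gene MIR671 (below 0.1 FPKM in library 1 and 134 in library 2), MIR221 and SNORD89, which were listed at 0 in library 1 and stood at 57.8 and 40.2 FPKM in library 2, and the ribosomal protein gene RPS28 (0.357 and 45.7), whose processed copies make it uncertain. Toward library 1 they were FGA, FGB, the vitamin D-binding protein gene GC (83.7 and 4.44 FPKM in libraries 1 and 2), the lipase inhibitor gene ANGPTL4 (103 and 6.59), the phosphate transporter gene SLC34A2 (51.1 and 2.98), SERPINA3 (103 and 7.71), SLPI (70.4 and 5.35), MT1A, SCNN1G, and the small RNA gene SNORA61, which was listed at 0 in library 2. SERPINA3 and SLPI encode protease inhibitors.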

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

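The alternatives without small RNA genes and, for list ratios, with members of at least 1 FPKM were chosen only after the data were seen. Of 163 recomputed list ratios, 147 stayed on their side of the random range and 0 changed direction after a call. In all, 21 of 34 lists kept their call under every alternative run, 13 of them outside the range. Scaling by the median ratio, a log2 factor of 0.07 before the pseudocount, changed no call. It moves a list and its random lists nearly alike, so it could hardly change a call, and its ratios are among the 163. Leaving out 1 library gives the other's value, which always lies within 1 SD of a mean of 2, so it says nothing about stability. Alternatives without mitochondrially encoded genes were not run because none was measured, and those for counts because the values are FPKM. Filters that left a list fewer than 3 members gave no list ratio, while contrasts were computed on as few as 1 member. The cause of each change below was not tested, except where a mean weighs abundant or strongly changed members more by construction.

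With the mean over members, list ratios fell inside the random range for the proximal tubule (0.32), its convoluted (0.58) and straight parts (-0.13), thick ascending limb (-0.16), distal convoluted tubule (0.48), myeloid cell (0.28), hypoxia (0.41), glycolysis (-0.092), drug transporter (0.26) and ribosomal protein lists (-0.091). Heat shock (0.61) and acute phase (-1.01) moved outside it. With a pseudocount of 0.1 hypoxia (0.30) fell inside. With members of at least 5 FPKM glycolysis (-0.12) fell inside and acute phase (-0.32) outside, and with members of at least 1 FPKM aquaporins, at 0.01 with all members (-0.19) moved outside.

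Detected genes in both libraries numbered 7309 at 5 FPKM. Over genes with a mean of at least 10 FPKM, Pearson's r was 0.892 and Spearman's rho 0.873, beyond the 0.05 allowed for no change. At a mean of at least 20 FPKM, 43 genes were 4-fold higher in library 2 and 11 in library 1. Without small RNA genes, 16 were higher in library 1.

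The log2 contrast of the proximal tubule became 3.46 over the straight part, 3.73 over intercalated cells, 6.08 over B and plasma cells and 5.98 over red blood cells with means over members. With a pseudocount of 0.1 it was 4.0 over intercalated cells, 7.37 over T and NK cells, 7.97 over B and plasma cells and 8.04 over red blood cells. With members of at least 1 FPKM it was 1.01 over the connecting tubule and principal cell list, 5.24 over T and NK cells, 4.03 over B and plasma cells and 4.08 over red blood cells. No contrast changed sign.

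Taking the mean over members moved these list levels, in FPKM, by more than 1 SD, to proximal tubule 309, straight proximal tubule 26.0, thin limb 115, thick ascending limb 212, distal convoluted tubule 21.6, connecting tubule and principal cell 77.1, intercalated cell 14.3, podocyte 11.1, endothelium 10.2, smooth muscle and mesangium 33.2, fibroblast and matrix 44.5, B and plasma cell 2.89, red blood cell 2.25, tubular injury 213, heat shock 133, metallothionein 970.4, interferon response 132, hypoxia 48.0, acute phase and complement 45, fatty acid oxidation 90.1, glycolysis 243, gluconeogenesis 729, nuclear oxidative phosphorylation 176, drug transporter 70.3, aquaporin 108, kidney transcription factor 15.1, inherited tubular disease 197, proliferation 3.56, housekeeping 417 and cytoplasmic ribosomal protein 401.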

Other observations

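Further gene lists, chosen after the data were seen, showed other groups that were higher in library 2. NF-kappa-B targets had a median log2 ratio of 1.35 (2.55-fold, random lists -0.10 to 0.28), with 10 of 12 members at least 2-fold higher, among them the monocyte chemokine gene CCL2 (21.1 and 162 FPKM in libraries 1 and 2) and the pathway inhibitor gene NFKBIA (43.2 and 94.6), while the chemokine gene CXCL2 stood at 6.69 and 3.57. Class I antigen presentation genes, without HLA genes, had a ratio of 0.75 (random lists -0.10 to 0.26), with B2M at 877 and 2623, the peptide transporter gene TAP1 at 14.7 and 26.7 and the immunoproteasome gene PSMB9 at 5.85 and 15.9. The integrated stress response list had a ratio of 0.51 (random lists -0.10 to 0.28) with members on both sides, from GDF15, a secreted stress protein (41.6 and 349.8), and PPP1R15A (8.68 and 67.0) to CHAC1 (6.83 and 2.32). Cholesterol synthesis genes had 0.34 (random lists -0.10 to 0.26), with SQLE at 3.25 and 9.22 FPKM.

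Other added groups did not differ between the libraries beyond random lists. The sodium potassium pump list had a ratio of -0.04 (random lists -0.13 to 0.29), with its subunit genes FXYD2 and ATP1B1 among the abundant transcripts (869 ± 25.1 and 765 ± 117 FPKM, SD, n = 2). Selenoprotein genes, to which GPX3 belongs, had -0.04 (random lists -0.11 to 0.25), although the selenium carrier gene SEPP1 stood at 231 and 445 FPKM in libraries 1 and 2 and GPX3 at 6984 and 10184.

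In the following, the tests of the interferon gamma list and of the second marker sets were written before their list ratios were computed, though single values of UBD, TAP1, PSMB8 and B2M had been seen. The tests of leukocyte genes, scale, myeloid against podocyte and stromal genes, immediate early against podocyte genes, and heat shock genes were chosen after the results were seen. Quartiles are over members with a mean of at least 1 FPKM, while list medians are over all members above 0 unless a filter is named. The design has 1 group and gives no biological condition to set against the technical explanations, so no such condition was tested as a cause of the 3 patterns.

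The interferon response list was higher in library 2 by a median log2 ratio of 3.80. More leukocytes in library 2 would bring their own markers to a like extent, but the upper quartile of the ratios of 16 leukocyte genes, of which CD68 (32.1 and 55.8 FPKM) was the most abundant, was 0.82, below the interferon list's lower quartile of 3.30. Of the 16, 13 were myeloid genes, 2 B and plasma cell genes and 1 a T and NK cell gene, so lymphocytes were hardly tested. A difference of scale would move all genes alike, but the upper quartile of the ratios of 12760 genes with a mean of at least 1 FPKM was 0.27, also below 3.30. A list of genes that respond more to interferon gamma, among them CD74 (424 and 473 FPKM) and GBP1 (5.39 and 13.2), was itself higher in library 2. Its median over 12 members was 0.38 (random lists -0.09 to 0.23). The upper quartile over its 9 members with a mean of at least 1 FPKM was 1.15, below 3.30, which argues against interferon gamma as the main driver. A response to type I or type III interferon in the tissue of library 2 may be a candidate explanation, and neither it nor a difference between persons or in handling was tested.

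Podocyte, endothelial, smooth muscle and fibroblast genes were higher in library 2, and a larger share of glomerular and stromal tissue after dissection could account for this. Such a share predicted that independent markers would follow, and 3 of 3 second marker sets lay above their random ranges, podocyte at 0.84, endothelium at 0.87 and smooth muscle and fibroblast at 0.78. The members of highest mean in these sets were CDKN1C (30.2 and 38.5 FPKM), TM4SF1 (22.6 and 53.9) and THY1 (61.2 and 137), and of the fixed lists 1 podocyte member, WT1, stands in another list, while their expression in tubule cells was not measured apart. A lower share of tubule alone would raise the markers of all other cell types alike, and the lower quartile of 1 of 7 fixed and second sets, the podocyte list at 1.05, exceeded the upper quartile of the myeloid ratios, 0.78. The other sets overlapped the myeloid ratios. A lower share of tubule would also lower tubule genes, but the tubule lists went both ways. The proximal tubule (0.29), its convoluted part (0.72) and the distal convoluted tubule (0.54) were higher in library 2. The straight part (-0.38), thick ascending limb (-0.35), intercalated cell (-0.33) and connecting tubule and principal cell (-0.74) lists were lower. Of the 8 convoluted members, 6 are also in the proximal list. With the mean over members, only the intercalated cell and connecting tubule and principal cell lists of these stayed outside their random ranges. The proximal list's median level was 131 and 113 FPKM in libraries 1 and 2. The ratios of 0.54 and -0.74 were those of TRPM6 and AQP4, each with a mean below 1 FPKM. A lower share of tubule was thus not decided and stays open, as does a change within podocyte, endothelial and stromal cells.

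Immediate early genes were higher in library 2 by a median log2 ratio of 2.26, and a larger share of non-tubular tissue would raise them no further than that tissue's own markers. Their lower quartile of 1.81 exceeded the podocyte list's upper quartile of 1.36, which argues against that share as the whole cause. Stress of the tissue before it was preserved may have raised them, for which heat shock genes were examined. Their median of 0.20 lay below the upper bound of 0.27 for random lists, with 6 of 11 members higher in library 2 and 5 higher in library 1. At least 2-fold higher were 3 members in library 2 and 0 in library 1. These 3 were HSPA6 and the copies HSPA1A (19.4 and 63.5 FPKM) and HSPA1B (18.5 and 70.2), and DNAJB1 stood at 62.7 and 118. The list's median was 0.00305 with members of at least 5 FPKM, within the random range, while the mean over members of 0.61 lay above its own. Stress before preservation could therefore not be decided.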
